A study of Homo sapiens with 4 samples.

How the data were processed

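Expression was measured on 4 Illumina bead arrays of 1 chip, 2 from MCFDCIS cells transfected with control siRNA and 2 from cells transfected with Slug siRNA. Per the labels' protocols, total RNA was extracted with a column kit 72 hours after transfection and amplified and biotin-labelled with a kit for Illumina arrays. The labels name the replicates of each group as biological replicates, and do not say whether they came from separate days or thawed stocks, so p-values measure the spread between these arrays.

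The values used were the deposited mean bead intensities per probe, on a linear scale and, per the file headers, not normalized, with the standard error and number of beads behind each. No background had been subtracted, since the lowest value was 80.4 intensity units. A detection p-value per probe and array was deposited with them, which ranks the probe among the negative control beads of its array. These p-values come in steps that imply 770 negative controls. The authors also deposited a table of normalized intensities, on a linear scale, whose 4 columns share a median of 10.7 and, when sorted, differ by at most 0.428 intensity units. It was used as an alternative only, after its columns were correlated with the arrays across probes (mean r = 0.984 with the same array, against 0.973 or lower with other arrays). How that table was background-corrected and which tool made it are not given in the sources used here. The table of bead values held 8 further columns of per-sample values (array counts and deviations), which were not used.

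The median number of beads per probe was 20 to 21 on each array, and the median standard error over beads was 3.57% of the signal of the probes kept. Bead error is not replicate error, and the number of arrays, 2 per group, limits the precision.

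Intensities were analysed in R 4.3.3 with limma 3.58.1. The mean and spread of the negative controls were inferred from the detection p-values, and the signals were background-corrected with the normal-exponential model, given an offset of 16, quantile normalized between arrays and put on a log2 scale. Probes were kept where the detection p was under 0.05 on at least 2 arrays, which left 19446 of 47323 probes. Gene symbols came from the platform annotation, which gave 1 symbol for 30113 probes, several for 8 and none for 17202. Of the probes with 1 symbol, 30074 matched a current gene identifier of the RefSeq annotation of assembly GRCh38.p14, and no symbol needed an update. Among the kept probes 14875 had 1 symbol and 4571 did not. The last were tested but not named, and 0 of them passed the threshold. Each of 11200 genes was represented by its kept probe with the highest mean, and the text says where the probes of a gene called as changed disagree. The files name no genome build, so no coordinates are given.

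Groups were compared with lmFit and eBayes with group as the only term (2 residual degrees of freedom, 5.11 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. An exact permutation test of a single gene cannot give a p below 0.333 with 2 against 2 arrays, so only model-based adjusted values are given. Fold changes are on the normalized log2 scale and are understated for dim probes, because the offset stays in the signal. For a gene not above background on either array of a group, a bound is given, set against the lowest signal among detected probes of those arrays. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 22 lists, each with at least 5 measured members. Camera compares a list with all other genes. In fry, PValue tests whether the genes of a list move, on balance, one way, and PValue.Mixed whether they change in either direction. A list's median was also set against 10000 random lists of the same size matched on mean signal. Figures were drawn with matplotlib 3.10.9.

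The comparison, thresholds, lists and alternatives were chosen before the data were examined, as was the rule for naming genes. The rule took SNAI2 and 13 context genes whatever their values, then the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold that have a named protein-coding gene, a detection p under 0.01 on both arrays of the higher group and no overlap between groups. Unfilled places went to the genes with the largest change that met the other conditions. From each list it took up to 4 members past the threshold, or the 2 with the largest change where none passed.

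The procedure was tested on 20 simulated data sets of 2 against 2 arrays with 19446 probes, 50 of them changed at each size. It recovered 0.6% of changes of 0.5 on the log2 scale, 18.7% of changes of 1, 79.2% of changes of 1.5 and 95.6% of changes of 2, with 5.8 false calls among 102.85 on average. A shift of -0.3 given to the hypoxia and glycolysis list was called by camera in 20 of 20 simulations over 11200 genes, with 1 false call among 420 tests of other lists. The simulated genes varied independently.

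The alternatives were other background corrections (normal-exponential without negative controls, none, an offset of 50), cyclic loess or median scaling, the authors' normalized table, no filter on dim probes or a stricter one (detection p under 0.01 on all arrays), an intensity trend or robust spread model, the replicate number as a term, each array left out in turn, the mean over a gene's probes, a threshold of 0.1, and the other list tests.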

Results

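Gene expression was profiled in MCFDCIS cells, a breast cancer cell line of the basal subtype, after transfection with a control siRNA or with siRNA against Slug. Slug is the protein product of SNAI2, a zinc finger transcription factor of the Snail family that represses epithelial genes such as CDH1. Total RNA was collected 72 hours after transfection and hybridised to 4 positions of 1 Illumina bead array chip, with 2 biological replicates of each transfection. Between 39.8% and 40.8% of the 47323 probes on an array had a detection p under 0.05. The negative control medians lay between 108 and 114 intensity units. Normalized log2 intensities correlated across probes at r = 0.989 between the control arrays and r = 0.991 between the Slug siRNA arrays, and at 0.981 to 0.988 between arrays of different groups. Probes are not independent replicates, so these correlations describe the arrays only. The number of arrays limits the precision of every value given here.

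The only comparison in the design asks how knockdown of Slug changes gene expression in this line. SNAI2 itself, the target of the siRNA, was measured by 2 probes, and both read lower in each Slug siRNA array than in either control array. The brighter probe had a log2 intensity of 8.98 ± 0.05 (SD, n = 2) with control siRNA and 8.54 ± 0.04 (SD, n = 2) with Slug siRNA, a ratio of 1.35 of control over Slug siRNA. Its log2 fold change was -0.44 (SE 0.16, limma adjusted p = 0.316), and that of the other probe was -0.37 (adjusted p = 0.429). Neither probe passed the adjusted threshold, and 806 of 11200 genes had a log2 fold change at least as low as that of SNAI2. For this target, fixed in advance, the unadjusted limma p was 0.027 for the brighter probe and 0.064 for the other. That threshold recovered 0.6% of simulated changes of 0.5, so missing it says little about a fall of this size. The related repressors SNAI1, SNAI3, ZEB1 and ZEB2 were not above background on any of the 4 arrays, and TP63 was not analysed here.

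**Figure D1:**
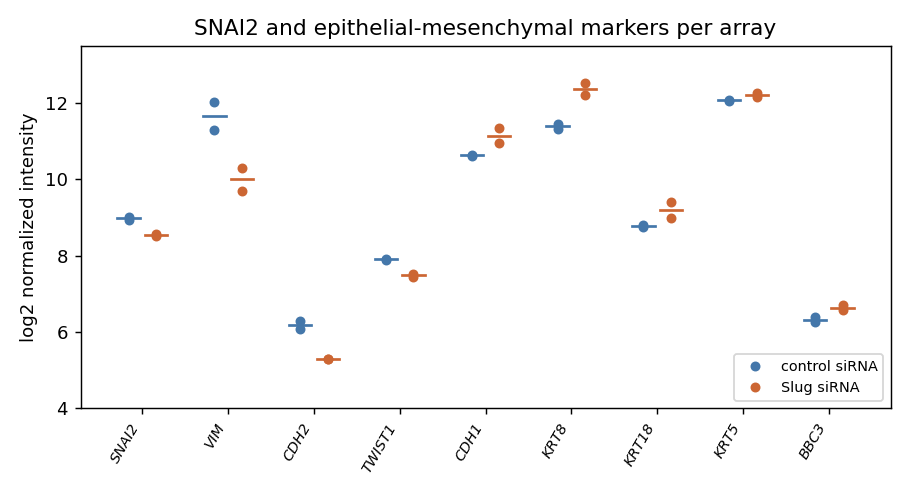
Normalized log2 intensity (vertical axis) of SNAI2 and of epithelial and mesenchymal marker genes (horizontal axis) on each array, with blue points for control siRNA, orange points for Slug siRNA and a bar at each group mean (2 arrays per group). SNAI2 averages 8.98 with control and 8.54 with Slug siRNA, CDH2 6.19 and 5.29, and KRT8 11.39 and 12.37, and none of the genes drawn passed the adjusted threshold.

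After Slug siRNA, 4 genes rose and 9 fell at a limma adjusted p under 0.05, and all 13 changed by at least 2-fold. TAGLN, which encodes the actin-binding protein transgelin, rose 5.84-fold, from a log2 intensity of 5.02 ± 0.01 to 7.57 ± 0.25 (SD, n = 2 each, adjusted p = 0.015). PRR15L, a proline-rich protein gene, rose 4.77-fold (log2 fold change 2.26, SE 0.17, adjusted p = 0.015). HPGD, the dehydrogenase that inactivates prostaglandins, rose 3.46-fold (log2 fold change 1.79, SE 0.17, adjusted p = 0.033), and YOD1, a deubiquitinase, rose 3.13-fold (log2 fold change 1.65, SE 0.17, adjusted p = 0.038). TAGLN was read by 2 probes, with log2 fold changes of 2.55 and 1.24, and the gene's value was 1.16 without background correction and 3.37 with the authors' normalized values.

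The deepest fall among the genes past the threshold was that of ANTXR1, a cell surface receptor that binds collagen and anthrax toxin. It went from 8.98 ± 0.05 with control siRNA to 6.69 ± 0.07 with Slug siRNA (SD, n = 2 each), a log2 fold change of -2.28 (SE 0.16, adjusted p = 0.015). Its 4 probes did not move alike, and their log2 fold changes spanned -2.28 to 0.19. With the mean over its probes the log2 fold change was -0.66 and no longer passed (adjusted p = 0.119). ADA, the adenosine deaminase of purine metabolism, and GSDME, a pore-forming gasdermin, both had a log2 fold change of -1.81 (adjusted p = 0.033 for each). Lower values followed for SLC49A4, a lysosomal membrane transporter (log2 fold change -1.77), FAM81A (-1.75), the metal-binding metallothionein MT1E (-1.68) and ANAPC1, a scaffold subunit of the anaphase-promoting complex (-1.65). GLCE, an epimerase of heparan sulfate synthesis, was 3.04-fold lower, and BCL7B, a subunit of SWI/SNF chromatin remodelling complexes, 2.84-fold lower. Their adjusted p values ranged from 0.033 to 0.041 (2 arrays per group). ANAPC1 had a second probe with a log2 fold change of -0.34, and its value was -0.998 with the mean over its probes. Without background correction the log2 fold changes were 0.78 for HPGD, -1.09 for ADA, -0.81 for FAM81A and -0.65 for BCL7B, each over 1.5 times nearer to 0.

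Other genes with large differences did not pass the threshold with group as the only term. CPA4, a carboxypeptidase, read 5.65 ± 0.58 with control and 8.34 ± 0.55 with Slug siRNA (SD, n = 2 each), a log2 fold change of 2.69 at an adjusted p of 0.055. Other genes with high positive values were KRT80, a type II keratin of differentiating epithelia (1.95, adjusted p = 0.076), KLK10, a secreted serine protease (1.89, adjusted p = 0.117), and SULT2B1, a sterol sulfotransferase (1.71, adjusted p = 0.074). PARD6A, a component of the Par polarity complex (1.59), GDPD3 (1.58), DMBT1, a secreted mucosal glycoprotein (1.57), and SYBU (1.56) completed that group, with adjusted p between 0.054 and 0.263. The second probes of SULT2B1 and PARD6A gave 0.57 and 0.83. On the other side, ALDH3A1, an aldehyde dehydrogenase, had a log2 fold change of -1.75 (adjusted p = 0.054), and NUP160, a nuclear pore subunit, one of -1.56 (adjusted p = 0.053). VIM, the mesenchymal intermediate filament vimentin, read 11.66 ± 0.51 (SD, n = 2) with control siRNA, 3.16 times its level with Slug siRNA. Its log2 fold change was -1.66 (SE 0.29, adjusted p = 0.084), and its second probe gave -1.83. With the replicate number as a term, which leaves 1 residual degree of freedom, all the genes of this paragraph passed limma's adjusted threshold. Their adjusted p then ranged from 0.0059 (CPA4) to 0.018 (SYBU), though the labels do not tie a number to a shared day or batch.

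**Figure D2:**
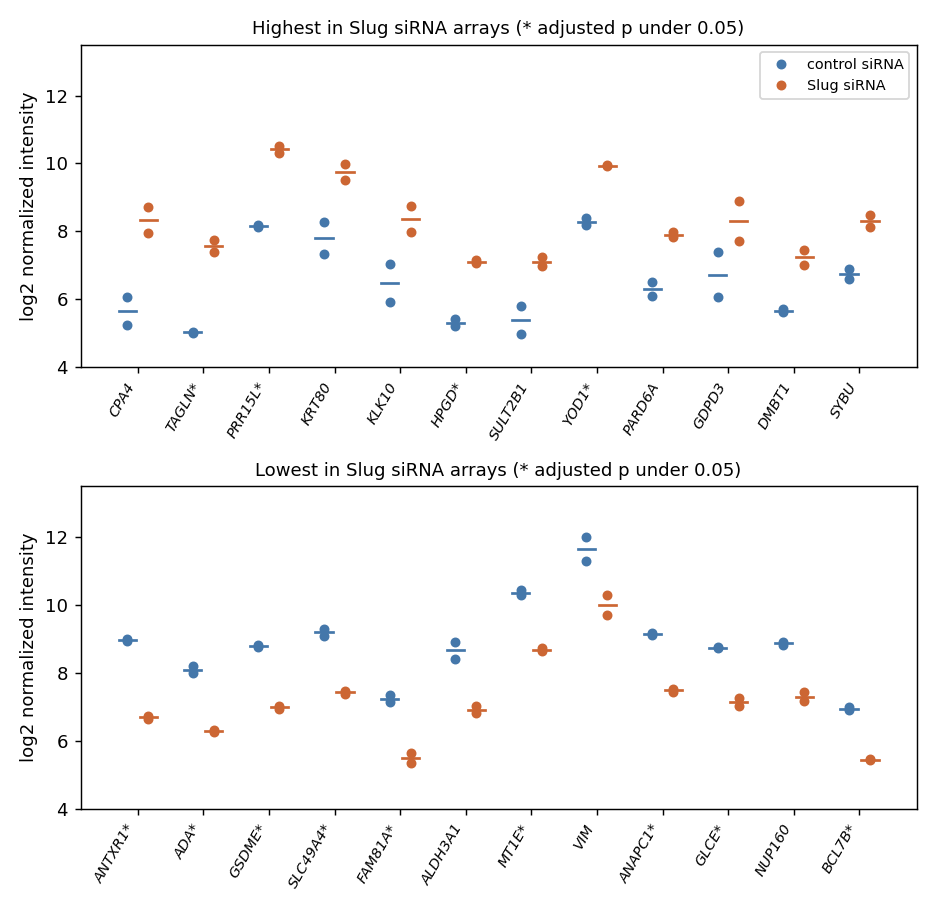
Normalized log2 intensity (vertical axis) of the 12 named genes highest in Slug siRNA arrays (upper panel) and the 12 lowest (lower panel), with a blue point for each control siRNA array, an orange point for each Slug siRNA array and a bar at each group mean. Asterisks mark the 4 genes that rose and the 9 that fell at an adjusted p under 0.05, and in each gene drawn the points of one colour lie above both of the other.

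At an unadjusted p under 0.05, 692 genes were higher and 769 lower with Slug siRNA. In 45.1% of the genes both arrays of one group lay above both of the other, where chance gives 33.3% on average. Among these, 64 genes were at least 2-fold higher and 87 at least 2-fold lower. Genes on the same arrays are not independent, and shares for other splits of the arrays are not given, so the excess alone is no evidence of an effect. The number of genes past the adjusted threshold moved from 13 to 0 with the authors' normalized values or with no filter on dim probes. It rose to 217 with a larger offset after background correction and to 361 with the replicate number as a term. With 1 array left out in turn it was 0 without control siRNA replicate 1, 9 without control siRNA replicate 2, 4 without Slug siRNA replicate 1 and 3 without Slug siRNA replicate 2.

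Relative to other genes, mesenchymal genes lay lower and luminal markers higher with Slug siRNA, and genes of hypoxia and glycolysis, inflammatory signalling and cholesterol synthesis lay lower. These were among 6 of 22 preset lists past an adjusted p under 0.05 in limma's camera test, which compares a list with all other genes at a preset correlation of 0.01. With an estimated correlation none of the 22 lists passed. That form takes its degrees of freedom from the 2 residual ones. The estimate was 0.796 for the S phase list, but -0.0246 to 0.0175 for the other 5, near the preset. For those 5 the loss came mainly with the few degrees of freedom. No list passed fry's test of a common direction, which makes no reference to other genes (adjusted p of 0.105 to 0.797 for the 6 lists). Fry's test of change in either direction passed for 12 of the 22 lists, 4 of them among these 6. It too makes no reference to other genes, and 1461 of all 11200 genes had an unadjusted limma p under 0.05. How often arbitrary lists would pass was not tested, so passing does not mark a list out. The adjusted p in this test was 0.0049 for the mesenchymal list, 0.013 for the luminal and cholesterol lists and 0.015 for hypoxia and glycolysis. It was 0.051 for the inflammatory list and 0.703 for the S phase list. The other 8 lists past it, with adjusted p from 0.0065 to 0.020, were those of epithelial, basal, keratinocyte, p53, TGF-beta, Notch, protease and unfolded protein genes. Where alternatives are counted below, fry stands for its test of a common direction. No member of these 6 lists passed the threshold over all genes, so their members are given by value.

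**Figure D3:**
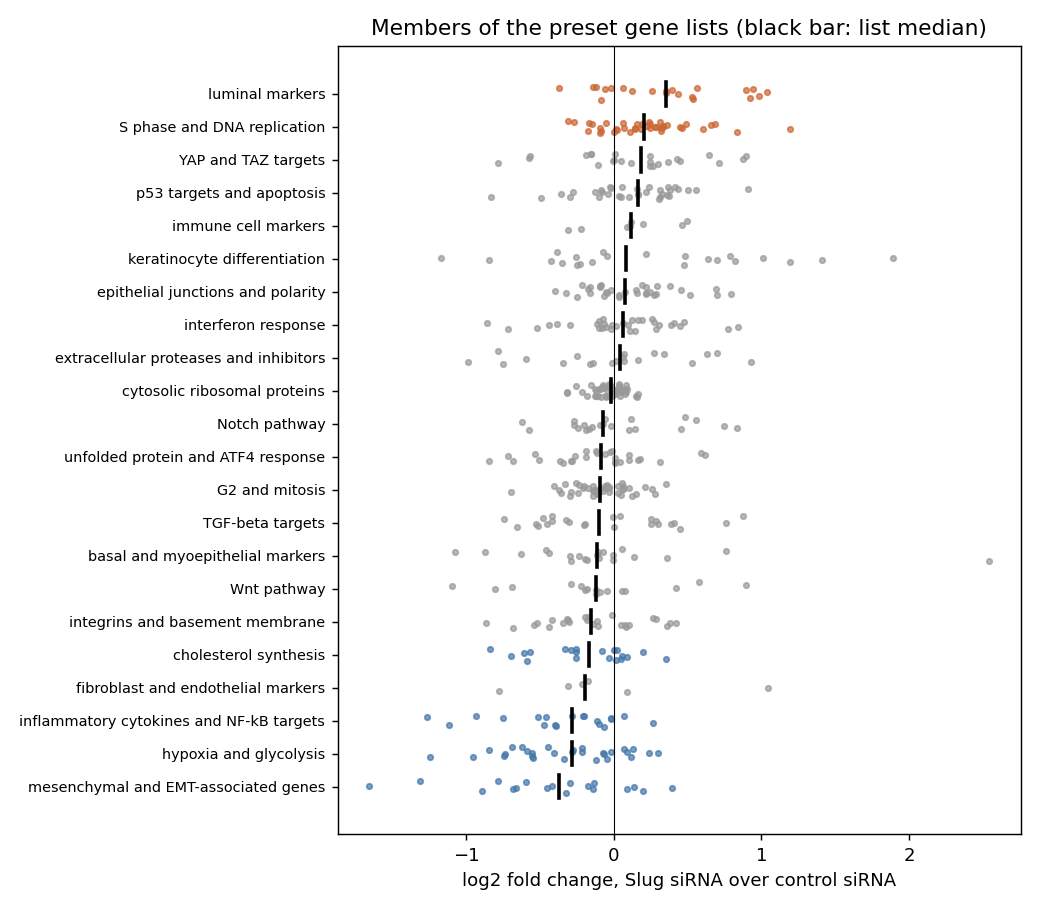
Log2 fold change of Slug over control siRNA (horizontal axis) for each measured member of the 22 preset gene lists (vertical axis), 1 point per gene, with a black bar at each list median. Lists past an adjusted p under 0.05 at the preset correlation are orange where the median is above 0 and blue where it is below 0, from 0.35 for the luminal markers to -0.37 for the mesenchymal genes, and the other lists are grey.

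The mesenchymal and EMT-associated list had a median log2 fold change of -0.37 over 18 measured members, of which 14 were negative (adjusted p = 5.0e-05). With an estimated correlation the adjusted p was 0.314. The list mean of -0.43 moved to -0.23 with no filter on dim probes (adjusted p = 0.0040) and to -0.52 with the authors' normalized values. No member passed over all genes, and 7 were lower when adjusted over the list alone. Besides VIM, the lowest values belonged to the transcription factor gene TWIST2 (-1.31, adjusted p = 0.055) and to CDH2, which encodes N-cadherin (-0.89, adjusted p = 0.092). TWIST1 stood at -0.42 (adjusted p = 0.334). The list of epithelial junction and polarity genes did not pass (33 members, median 0.07, adjusted p = 0.140), and no member passed when adjusted over the list alone. CDH1, the gene of E-cadherin, had a log2 fold change of 0.52 (SE 0.19, adjusted p = 0.317), and the polarity gene LLGL2 one of 0.80 (adjusted p = 0.163). The tight junction gene CLDN3 was not above background with control siRNA. Its mean with Slug siRNA was at least 1.28-fold higher (adjusted p = 0.281). This bound holds for the mean only, since the 2 Slug siRNA arrays read 5.59 and 4.98 on the log2 scale.

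Luminal markers had a median log2 fold change of 0.35, with 15 of 21 measured members positive (adjusted p = 8.1e-04), and 7 members were higher when adjusted over the list alone. With an estimated correlation the adjusted p was 0.314. CEACAM6, a cell surface adhesion molecule, stood at 1.04 (adjusted p = 0.107). The simple epithelial keratin KRT8 read 11.39 ± 0.10 with control and 12.37 ± 0.23 with Slug siRNA (SD, n = 2 each), a log2 fold change of 0.99 (adjusted p = 0.092). Its partner KRT18 stood at 0.43 (adjusted p = 0.417), with 0.08 from its second probe. The basal and myoepithelial list did not pass (21 members, median -0.12, adjusted p = 0.246), although 16 members were negative. It held TAGLN, the only list member past the threshold over all genes, and when adjusted over the list alone 2 members were higher and 3 lower. KRT5, a basal keratin, had a log2 fold change of 0.14 (adjusted p = 0.799). Keratinocyte differentiation genes were split evenly, with 11 of 22 positive (median 0.09, adjusted p = 0.257), and when adjusted over the list alone 5 were higher and 2 lower. KLK10 and the cornified envelope gene SPRR3 (1.41, adjusted p = 0.301) had the largest values there. Without Slug siRNA replicate 1 the mean of this list went from 0.25 to 0.48, and over all alternatives it ranged from 0.03 to 0.48. The list's median differed by 0.35 between replicate 2 and replicate 1. Camera gave that difference an adjusted p of 0.0053 at the preset correlation. With an estimated correlation, on 1 residual degree of freedom, the adjusted p was 0.874.

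Genes of hypoxia and glycolysis had a median log2 fold change of -0.29, and 23 of 29 members were negative (adjusted p = 2.4e-05). With an estimated correlation the adjusted p was 0.314. When adjusted over the list alone 8 members were lower. The glycolytic aldolase ALDOC stood at -1.24 (adjusted p = 0.069) and the hypoxia-inducible gene NDRG1 at -0.95 (adjusted p = 0.154). Inflammatory cytokines and NF-kB targets had a median of -0.28 with 17 of 19 members negative (adjusted p = 0.0013, and adjusted p = 0.314 with an estimated correlation), and 1 member was lower when adjusted over the list alone. The neutrophil chemokine CXCL1 read 11.32 ± 0.12 with control and 10.05 ± 0.01 with Slug siRNA (SD, n = 2 each, adjusted p = 0.055), and the interleukin gene IL1B stood at -1.11 (adjusted p = 0.219). With no filter on dim probes the mean of the inflammatory list went from -0.37 to -0.19, and the list no longer passed (adjusted p = 0.057). Cholesterol synthesis genes had a median of -0.17, with 12 of 20 members negative (adjusted p = 0.026, and adjusted p = 0.420 with an estimated correlation). When adjusted over the list alone 5 were lower, and INSIG1, a sterol sensor, and FDPS, a synthase of the mevalonate pathway, stood at -0.84 and -0.70 (adjusted p = 0.186 and 0.177). The cholesterol call was lost without control siRNA replicate 2 (adjusted p = 0.099) and without Slug siRNA replicate 1 (adjusted p = 0.134), where the list mean, -0.20 over all arrays, was -0.17 in both.

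S phase and DNA replication genes had a median of 0.21 with 31 of 40 members positive (adjusted p = 0.032), and no member passed when adjusted over the list alone. With an estimated correlation the adjusted p was 0.773. The cyclin gene CCNE1 stood at 1.19 (adjusted p = 0.254) and POLE2, a DNA polymerase epsilon subunit, at 0.83 (adjusted p = 0.292). Without control siRNA replicate 1 CCNE1 was 0.67 and POLE2 0.44, and without control siRNA replicate 2 they were 1.71 and 1.23. The S phase list had a median of 0.52 for replicate 2 minus replicate 1, and 36 of its 40 members were higher in replicate 2 of both groups. Camera gave this replicate difference an adjusted p of 5.3e-18 at the preset correlation and 0.874 with an estimated one. The estimated form takes its degrees of freedom from the residual ones, 1 in this fit. It can hardly pass there, so 0.874 does not argue against a replicate difference. Integrin and basement membrane genes (-0.22, adjusted p = 0.027), extracellular proteases (-0.13, adjusted p = 0.033) and fibroblast and endothelial markers (-0.35, adjusted p = 0.033) also passed between replicate numbers at the preset correlation, and no list did so with an estimated one. The S phase mean log2 fold change, 0.21 over all arrays, was -0.08 without control siRNA replicate 1 and 0.02 without Slug siRNA replicate 2. With other arrays left out it reached 0.51. Leaving out 1 array unbalances the replicate numbers, so these values mix the group difference with the replicate difference. With the replicate number as a term, camera's adjusted p was 0.0013 at the preset correlation. That preset lies far below the 0.796 estimated for this list with group as the only term. The camera call with group as the only term was lost with median scaling (mean 0.25, adjusted p = 0.0595). It was also lost with the authors' normalized values (mean 0.21, adjusted p = 0.0808), with the mean about as high in both. G2 and mitosis genes did not pass (43 members, median -0.10, adjusted p = 0.131). Their Slug siRNA minus control median was 0.08 in replicate 1, with 15 members lower, and -0.28 in replicate 2, with 38 lower. The list mean was -0.13 without control siRNA replicate 1, -0.22 without Slug siRNA replicate 1 and 0.04 without Slug siRNA replicate 2. Its estimated correlation was 0.48. No member passed when adjusted over the list alone. The proliferation marker MKI67 and the mitotic kinase AURKA stood at -0.70 (adjusted p = 0.190) and -0.40 (adjusted p = 0.382).

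None of the remaining lists passed camera in the planned comparison, but 3 of them passed in some of the 18 alternatives, and 5 passed fry's test of change in either direction (p53, TGF-beta, Notch, proteases and unfolded protein). Targets of p53 and apoptosis genes had a median of 0.16 (34 members, adjusted p = 0.119), with BBC3, the apoptotic effector PUMA, at 0.31 (adjusted p = 0.496), TP53INP1 at 0.91 (adjusted p = 0.199) and BIK at -0.83 (adjusted p = 0.140). This list passed in 2 of 18 alternatives, without background correction (adjusted p = 0.041) and with no filter on dim probes (adjusted p = 0.046), and in fry's test of change in either direction (adjusted p = 0.015). Integrin and basement membrane genes had a median of -0.16 (26 members, adjusted p = 0.119), with the collagen gene COL4A6 at -0.87 and the integrin gene ITGA5 at -0.68, and the list passed without control siRNA replicate 2 (adjusted p = 0.0030). Genes of the unfolded protein and ATF4 response had a median of -0.09 (28 members, adjusted p = 0.0998), with VLDLR at -0.85 and PDIA4 at -0.71. It passed in 6 of 18 alternatives, at adjusted p between 0.033 and 0.0498, and reached 0.501 in the others, while fry's test of change in either direction gave 0.014. YAP and TAZ targets had a median of 0.18 (24 members, adjusted p = 0.246), with DKK1 at 0.90 and TGFB2 at 0.88. For Wnt pathway genes the median was -0.12 (16 members, adjusted p = 0.297), with the receptor FZD2 at -1.10. TGF-beta targets stood at -0.10 (24 members, adjusted p = 0.332, and 0.015 in fry's test of either direction), with ID2 at 0.76, and interferon response genes at 0.06 (33 members, adjusted p = 0.567), with PSMB9 at -0.86 (0.02 from its second probe) and ISG15 at 0.84. The Notch list had a median of -0.08, a mean of 0.02 and a downward test (21 members, adjusted p = 0.982, and 0.013 in fry's test of either direction), with HEY1 at 0.83 and LFNG at 0.75 (0.12 and 0.20 from their second probes). Extracellular proteases and inhibitors had a median of 0.04, a mean of -0.01 and an upward test (20 members, adjusted p = 0.982, and 0.0078 in fry's test of either direction), with MMP7 at -0.99 and ADAM8 at 0.93. Cytosolic ribosomal protein genes had a median of -0.02 (50 members, adjusted p = 0.517), with RPL29 and RPL37 both at -0.32. When adjusted over the list alone, 1 TGF-beta target was higher and 2 were lower, 3 proteases or inhibitors were higher and 3 lower, and 2 genes of the unfolded protein and ATF4 response were higher and 3 lower. No member of the p53, integrin, YAP and TAZ, Wnt, interferon, Notch or ribosomal lists passed that adjustment.

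Most markers of other cell types were not measured, and whether they lacked signal or a named probe is not given here. Of 24 immune cell markers 8 were measured, with a median of 0.11 (adjusted p = 0.517), among them CD2 at 0.50 and CD14 at 0.46, and none passed when adjusted over the list alone. Of 22 fibroblast and endothelial markers 6 were measured, with a median of -0.19 (adjusted p = 0.567). The fibroblast protease gene FAP stood at 1.05 (adjusted p = 0.091) and was the 1 member higher when adjusted over the list alone, while the endothelial adhesion gene PECAM1 stood at -0.78 (adjusted p = 0.280). Of the 6 genes in that list, S100A4 and COL1A1 are also in the mesenchymal list.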

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

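Every alternative here was chosen before the data were examined. The 13 genes past the threshold kept their direction in each alternative that measured them, which was all 13 in each except the stricter filter on dim probes (11 of 11), and their number depended on several settings. Of the 13 log2 fold changes, those of TAGLN (1.16 to 3.37), HPGD (0.78 to 2.33), ANTXR1 (-2.44 to -0.66), ADA (-2.01 to -1.09), FAM81A (-2.19 to -0.81), ANAPC1 (-1.71 to -0.998) and BCL7B (-1.92 to -0.65) moved by over 1.5 times in some alternative. Several named genes that did not pass moved widely too. GDPD3 ranged from 0.94 to 2.23, DMBT1 from 0.75 to 1.91, SPRR3 from 0.54 to 2.33 and DKK1 from 0.33 to 1.45. The range was 0.33 to 1.35 for ISG15, -1.60 to -0.45 for IL1B, -1.89 to -0.48 for TWIST2 and -1.29 to -0.32 for CDH2. Genes higher, lower and at least 2-fold, which numbered 4, 9 and 13, became 85, 126 and 59 with normexp without negative controls, 66, 92 and 36 without background correction, and 89, 128 and 68 with an offset of 50. They were 12, 22 and 34 with median scaling, 46, 78 and 94 with the stricter filter, 89, 127 and 125 with an intensity trend, 30, 39 and 67 with the mean of probes, and 62, 90 and 114 at a threshold of 0.1. The authors' normalized values gave 0, 0 and 0 in limma, with 1284 genes at an unadjusted p under 0.05, and no filter on dim probes gave 0, 0 and 0, with 2385. Cyclic loess (4, 10 and 14) and robust hyperparameters (4, 9 and 13) stayed close. The share of calls that were higher, 30.8%, was 41.8% without background correction and 41.0% with an offset of 50. The cause of these shifts was not tested. With 1 array left out, which leaves an arm with a lone array assumed to vary like the others, the counts ranged from 0 to 8 higher, 0 to 1 lower and 0 to 9 at least 2-fold, and 3 of the 13 genes were called again without control siRNA replicate 2, without Slug siRNA replicate 1 or without Slug siRNA replicate 2.

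The replicate block gave 156 genes higher, 205 lower and 149 at least 2-fold with 1 residual degree of freedom. The labels give no shared day or batch for a number. Same-numbered arrays had neighbouring position letters on the chip, A and B for replicate 1, I and J for replicate 2. With 2 pairs, they may share more than the number. Deviations of same-numbered arrays from their group means correlated at r = 0.36 across probes.

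SNAI2 stayed between -0.47 and -0.36 and past no threshold in 16 alternatives (adjusted p 0.134 to 0.732). Between 5 and 8 lists passed in the other settings, and 0 with an estimated correlation and 0 with fry's test of direction, whose lowest adjusted p was 0.105 (hypoxia and glycolysis), while 12 passed its test of change in either direction. Of the 6 lists past the threshold, the S phase list had an estimated correlation of 0.796, far above the preset 0.01, so its call rests on that setting. The other 5 had estimates from -0.0246 (cholesterol synthesis) to 0.0175 (hypoxia and glycolysis), and the estimated form takes its degrees of freedom from the 2 residual ones. Mean shifts that changed sign were those of 5 lists and of RPL37. For extracellular proteases the mean was 0.02 with median scaling, 0.012 with no filter, 2.8e-04 with the stricter filter, 0.0057 with the mean of probes and -0.12 to 0.12 with 1 array left out. For fibroblast and endothelial markers it was 0.024 with no filter, 0.016 with the mean of probes and -0.21 to 0.15 with 1 array left out. With 1 array left out the S phase list ranged from -0.083 to 0.51, Notch from -0.057 to 0.13, G2 and mitosis from -0.22 to 0.043, and RPL37 from -0.75 to 0.11. Leaving out an array unbalances the replicate numbers, between which the S phase median differs by 0.52. Camera's adjusted p for that difference was 0.874 with an estimated correlation, on 1 residual degree of freedom.

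Signal over background limits dim genes: the brighter SNAI2 probe read 4.81 times the negative control level and CDH2 1.37 times.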

Other observations

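The tests of explanations in this part were chosen only after the results were seen, except that leaving out each array was planned. The 8 gene families described here were also picked after their values were seen, several for members with large values, so they are given as values with no test. Kallikrein-related peptidases, secreted serine proteases of stratified epithelia, were positive in 5 of 5 measured genes, with a median log2 fold change of 0.77, led by KLK10 at 1.89 and KLK6 at 1.20. The epithelial sodium channel subunits SCNN1B (1.22), SCNN1G (1.19) and SCNN1A (0.26), which form the channel for sodium uptake across epithelia, were positive in 3 of 3. Keratins were positive in 10 of 14 (median 0.43), from KRT80 at 1.95 and KRT8 at 0.99 to KRT14 at -0.30. S100 proteins, small calcium-binding proteins, were positive in 3 of 13 (median -0.18), with S100A9 at -0.84. No member of these 4 families passed the threshold over all genes. The medians kept their sign under cyclic loess, median scaling and the authors' normalized values, but their size was less stable. With no filter on dim probes the keratin median was 0.04, the kallikrein median 0.09 and the S100 median -0.11. The sodium channel median of 1.19 was 0.71 without background correction. The keratin median was 0.22 without Slug siRNA replicate 2, and the kallikrein median was 1.43 without Slug siRNA replicate 1. The S100 median was -0.28 without control siRNA replicate 2 and -0.28 without Slug siRNA replicate 1.

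The other 4 families had medians near 0 or medians that changed sign. Metallothioneins had MT1E, which fell, beside MT1G at -0.46, MT2A at 0.02, MT1X at 0.04 and MT1F at 0.05. Their median of 0.02 was -0.04 with cyclic loess, -0.03 with median scaling and -0.25 without Slug siRNA replicate 1. The median of clade B serpins, 0.16, was -0.14 without control siRNA replicate 1 and 0.54 without control siRNA replicate 2. That of aldehyde dehydrogenases, -0.05, was -0.14 without Slug siRNA replicate 1, and that of 238 ZNF zinc finger genes was 0.06.

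SNAI2 RNA read only a little lower in the cells transfected with siRNA against it, while the brightest probes of TAGLN and ANTXR1 had log2 fold changes of 2.55 and -2.28. Both values depend on the processing, and ranged from 1.16 to 3.37 for TAGLN and from -2.44 to -0.66 for ANTXR1 over the alternatives. Subtracting each array's negative control median, without normalization between arrays, left a log2 fold change of -0.39. The value of -0.36 without background correction was quantile normalized, so the pair does not show how far background compressed the fold. With the negative control level removed, the fall stayed small. The main value of -0.44 was already corrected with those controls, so compression by background that they do not capture was not tested. A fault of one probe is argued against by the second probe, at -0.37. An exchange of control and Slug siRNA arrays of one replicate number would make crossed pairs the more alike, yet the higher of their correlations was 0.986, below 0.989 for the lower pair within a group. A partial loss of SNAI2 RNA at 72 hours, or loss mainly of the protein, may remain, and neither was tested. Whether the changes in other genes follow from loss of Slug cannot be told from a lone comparison of Slug siRNA with control siRNA.

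The hypoxia and glycolysis list lay lower with Slug siRNA by a median of -0.29, a call made by camera at the preset correlation. It was lost with an estimated correlation (adjusted p = 0.314) and in directional fry (adjusted p = 0.105). The estimate, 0.0175, was near the preset 0.01, and the loss came mainly with the 2 residual degrees of freedom of that form. A general shift of genes of like signal is argued against, since the list's median lay at percentile 0 of 10000 random lists matched on mean signal. Their central range was -0.07 to 0.09. Random lists ignore the correlation between genes and the spread between arrays, and the S phase list lay at percentile 100. The percentile therefore does not bear on chance differences between cultures. Leaving out any 1 array left the list mean at -0.31 or lower (adjusted p at most 1.0e-04 at the preset correlation, and 0.314 over all arrays with an estimated one), and the replicate numbers differed by a median of -0.058. Lower expression of these genes after Slug siRNA is a hypothesis consistent with these values, but cell density and oxygen at lysis could differ between dishes with the transfection and were not tested.

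The S phase list is less clear. Its Slug siRNA minus control medians were 0.29 in replicate 1 and 0.11 in replicate 2. A shift shared by the arrays of a replicate number cancels in the comparison of groups, but chance differences between cultures beyond it cannot be told apart from an effect of the siRNA, because the medians differ by 0.18, nearly as much as the list's shift of 0.21, with 2 replicates.

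On control siRNA replicate 1, 4 probes lay more than 2 log2 units outside the other 3 arrays, among them C6orf52 and SLC4A5, read from 81 and 80 beads where the array median was 20, and ERGIC1, read from 8.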
